A study of Mus musculus with 47 samples.

How the data were processed

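RNA of sorted mouse cells was measured on 47 Affymetrix arrays in 9 groups, with groups, replicate numbers, stage names and amplification kits taken from the labels. The deposited values are log2 intensities that the authors made with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes arrays and summarises the probes of each probe set. The notes do not state whether all arrays were processed together or whether a batch correction followed. The table held 45101 probe sets with 0 missing values, from 0.87 to 15.04, and the correlation between arrays ran from 0.756 to 0.993. Signal over background, and not a read depth, sets which genes can be compared. No array was left out of the analysis.

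Of the probe sets, 64 were controls, 932 carried several gene symbols and 9211 carried none. The 34958 probe sets with 1 symbol stood for 18194 genes, and 34754 of them were matched by gene identifier to the mouse gene table. Each gene was represented by its probe set with the highest mean, and 7711 of the tested genes had more than 1 probe set. A gene was tested when at least 3 arrays exceeded 5.14, the median of all values, which left 13134 genes. Of 435 named pairs called between groups, 159 had a group mean under that value, where the log2 difference is taken against signal near background and its exact size is uncertain. Probe sets of related genes, such as the MHC genes, can bind each other's transcripts.

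Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with all 9 groups and a term for the amplification kit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 10 comparisons, 9 between groups and 1 between the change in culture and the change in the animal. Values are log2 differences ± SE, and group levels are means ± SD. All tests were two-sided. The labels do not state whether replicates came from separate sorts or animals, so p-values measure only the spread between these arrays. That spread was estimated once per gene over all 9 groups, and not from the groups compared alone. Groups differ in it: correlations within a group ran from 0.776 to 0.992 in FL12.5 and from 0.971 to 0.984 in FL13.5. What the arrays with no kit named were amplified with is not stated either. The sort gates differ between most groups, and the cultured cells came from a cross of mouse strains while the animals were C57BL/6. The cited differentiation protocol has inducible Hoxb4 and Cdx4. None of these can be separated from the group differences.

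The comparisons, tests, filter, 30 gene lists, named-gene rule and most alternatives were chosen before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 300 tests, and repeated with an estimated correlation and with fry, which tests whether the genes of a list move one way without comparing them with other genes. The list tests with only the FL12.5 arrays labelled definitive were adjusted over 300 tests too, together with those of the other 8 comparisons. Of 76 list calls, 1 held with an estimated correlation, the fall of immediate early and stress genes from AGM to FL12.5, and the other calls were lost. Fry called 101, among them 69 of the 76. Genes were named by rule: the 6 largest rises and falls without overlap between the groups' arrays, then up to 3 members of each of at most 6 called lists, with 3 and 2 in the smaller comparisons. Sort markers, sex-linked genes and called members of the stem cell factor, Hox, Notch, imprinted, interferon and MHC lists were named beside these. Of 497 named pairs of a gene and a comparison that were called, 262 had several tested probe sets. In 5 pairs a probe set was called the opposite way: Xaf1 in 3 comparisons, Impact in EB against yolk sac, and H2-D1 in ESC-HSC against bone marrow.

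The alternatives tried were no amplification term, each kit alone, other uses of the probe sets, no filter and a stricter filter, array weights, moderation with a trend, renewed scaling, only the groups compared, the replicate number as a block, the FL12.5 arrays of each stage name alone, and leaving out each array. Alternatives without some AGM, yolk sac, placenta or FL12.5 arrays were added after the data were seen. Up to 100 other splits of the arrays were drawn for each comparison. The procedure was tested on simulated data with 200 changed genes per comparison, at 1.5-, 2- and 4-fold.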

Results

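Expression was measured on 47 Affymetrix arrays of blood stem cells and their precursors, sorted from mouse tissues or from differentiating embryonic stem cells. The in vivo groups were yolk sac at embryonic day 9 (n = 5), the aorta-gonad-mesonephros region (AGM) at day 11.5 (n = 6), placenta at day 12.5 (n = 6), fetal liver at days 12.5 (FL12.5, n = 6), 13.5 (FL13.5, n = 4) and 14.5 (FL14.5, n = 6), and adult bone marrow (n = 5). The in vitro groups were embryoid body cells at differentiation day 6 (EB, n = 6) and stem-cell-like cells at differentiation days 10 to 14 (ESC-HSC, n = 3). By the labels, yolk sac and EB cells are of a yolk-sac-like stage, AGM and placenta are specifying, and FL13.5, FL14.5, bone marrow and ESC-HSC are definitive. The FL12.5 arrays carry both later stage names, definitive on replicates 1, 4, 5 and 6 and specifying on replicates 2 and 3. RNA of 31 arrays was amplified with a Nugen kit, and 16 arrays name no kit. Array medians lay between 5.02 and 5.28 on the log2 scale, and the number of arrays limits the precision of every value.

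The groups were separated by their sort markers as well as by tissue. Kit, the stem cell factor receptor, had a mean log2 level of 10.12 ± 0.19 (SD, n = 5) in yolk sac, 10.63 ± 0.13 (n = 6) in FL14.5 and 11.25 ± 0.31 (n = 5) in bone marrow, but 7.58 ± 1.24 (n = 6) in AGM, whose gate did not use it. Cells sorted without CD45 and CD34 on their surface, the ESC-HSC, had the lowest Cd34 mean, 5.65 ± 1.09 (n = 3), and a Ptprc (CD45) mean of 7.52 ± 0.998, against 10.62 ± 0.16 (n = 6) in FL14.5. Slamf1, which encodes CD150, had means of 7.69 ± 0.39 (n = 6) in FL14.5 and 8.39 ± 0.34 (n = 5) in bone marrow, both sorted on it, and 10.28 ± 0.07 (n = 3) in ESC-HSC, which were not. Cd48 was highest in ESC-HSC, at 12.29 ± 0.15 (n = 3). Xist, the RNA that silences an X chromosome, had a mean of 11.27 ± 0.15 (n = 6) in FL14.5 and 5.46 ± 0.44 (n = 6) in EB. In ESC-HSC the Xist mean was 5.58 ± 0.43 (n = 3). In bone marrow it was 11.60 on replicate 5 and between 3.58 and 5.04 on the other replicates. The sexes are not stated, so sex cannot be separated from the group differences. Hoxb4 and Cdx4, transcription factors known to promote blood formation from embryonic stem cells, are the inducible factors of the cited differentiation protocol. Effects of inducing them cannot be separated from those of culture. Hoxb4 had its lowest group mean in ESC-HSC, 6.02 ± 0.33 (n = 3), and means of 6.75 to 7.46 in the other groups. Cdx4 group means lay between 2.28 and 2.53, below the filter on dim genes. In FL12.5, Kit was 5.50 and 4.63 on replicates 2 and 3 and between 10.04 and 10.91 on the other replicates. Cdh5, which encodes the sort marker VE-cadherin, was 9.94 and 9.87 on replicates 2 and 3 and between 6.13 and 6.92 on the others.

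**Figure D1:**
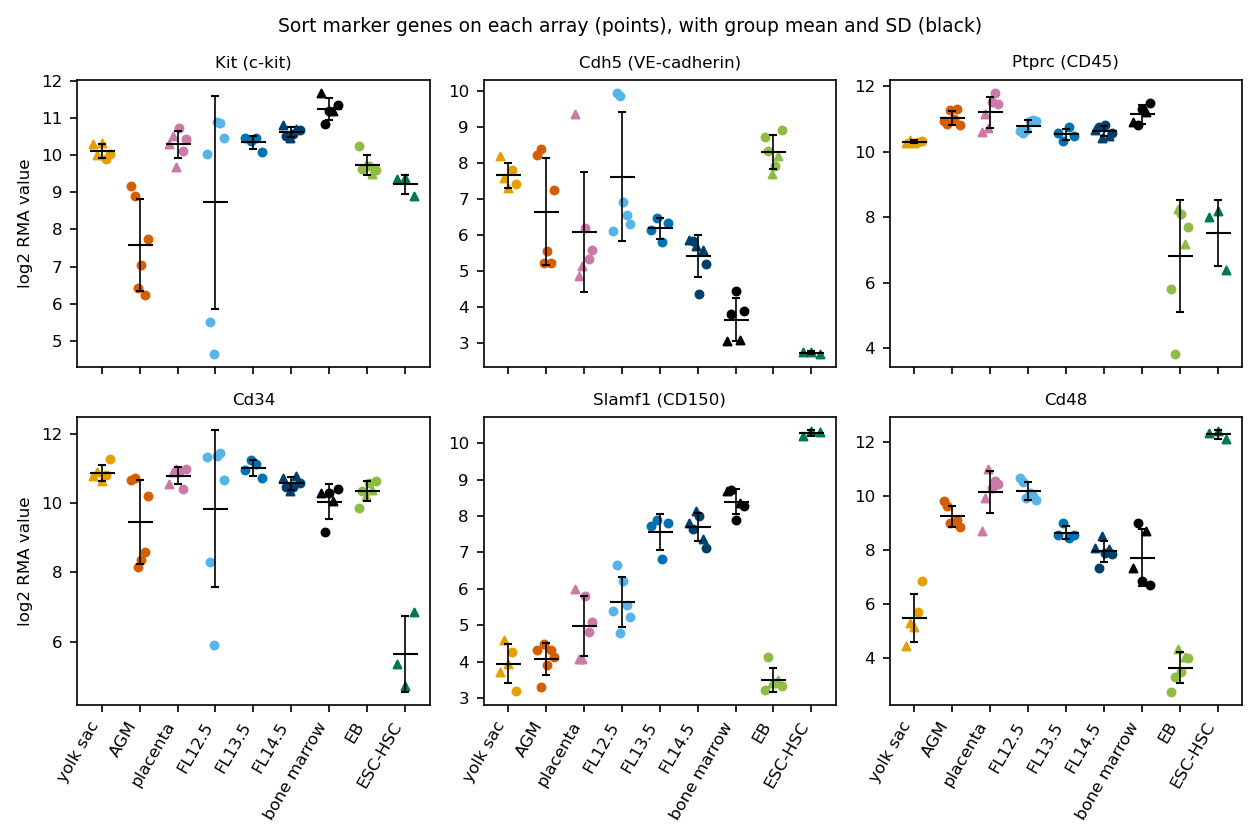
Log2 RMA values of 6 sort marker genes on each of the 47 arrays, by group, as points (circles for the Nugen kit, triangles for no kit named), with the group mean and SD in black. Kit was 5.50 and 4.63 on FL12.5 replicates 2 and 3, below every other array in the Kit panel.

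The first principal component of the 13134 tested genes held 26.3% of the variance and the second 18.8%. Of the variance of the first component, 80.6% lay between groups. FL12.5 replicates 2 and 3 had scores of 74.5 and 84.1 on it, inside the range of the AGM arrays (58.6 to 91.5), and the other FL12.5 arrays lay between -27.5 and -26.2.

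**Figure D2:**
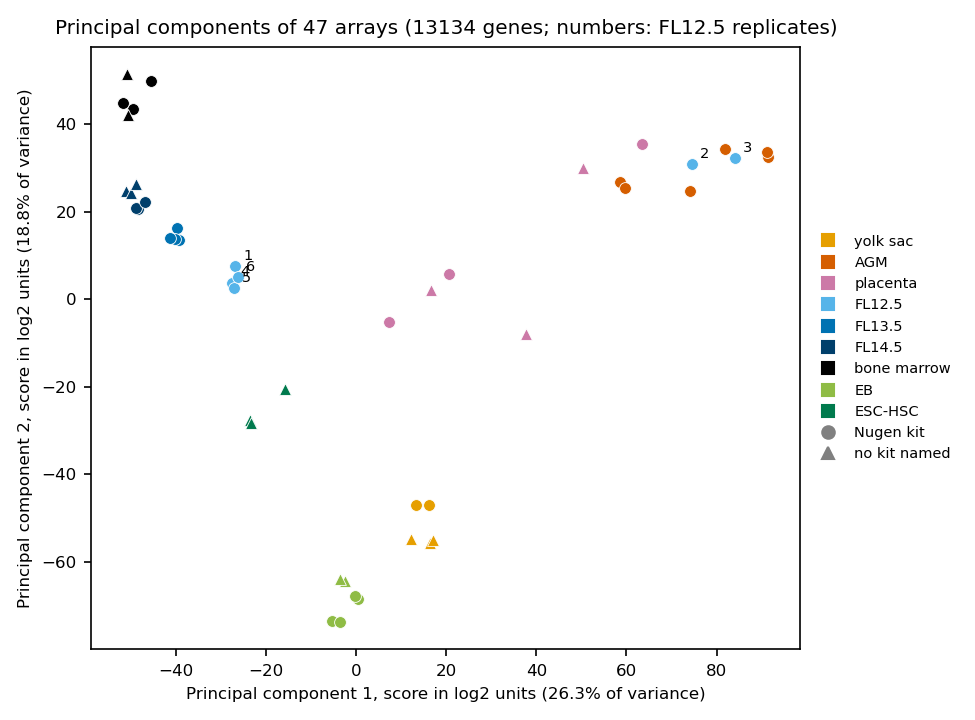
Scores of the 47 arrays on the first and second principal components, in log2 units, with groups in colour and the kit as the marker shape. FL12.5 replicates 2 and 3 lie among the AGM arrays, and the other FL12.5 arrays lie nearer to the later fetal liver arrays.

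AGM cells were compared with yolk sac cells to follow the step from the earliest blood precursors to the specifying stage. The largest rises among genes whose arrays did not overlap between the groups included macrophage genes. C1qa, a subunit of complement C1q, was 234-fold higher in AGM (log2 difference 7.87 ± 1.03 SE, adjusted p = 1.08e-07, n = 6 and 5). Aif1, a macrophage calcium-binding protein, was 186-fold higher (7.54 ± 1.11), and Cd83, a marker of activated antigen-presenting cells, 205-fold higher (7.68 ± 0.62). Among the genes that fell were Trim71, a repressor of translation in early development, which fell by 4.83 ± 0.43 on the log2 scale (adjusted p = 1.91e-11), and Sall4, a stem cell transcription factor, which fell by 4.10 ± 0.46 (adjusted p = 4.84e-09). Of 22 measured myeloid and macrophage markers, 18 rose and 0 fell, also 18 and 0 when adjusted over the list alone. Their median log2 difference was 3.33 (adjusted p = 2.87e-08, and adjusted p = 0.273 with an estimated correlation).

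Interferon response genes were higher in AGM, with 19 of 28 measured members called and 0 lower (24 adjusted over the list alone; adjusted p = 2.87e-08, and adjusted p = 0.577 with an estimated correlation). Rtp4 rose by 5.45 ± 0.55 and Gbp2, an interferon-induced GTPase, by 3.15 ± 0.48. Antigen processing followed, with 9 of 11 MHC class I genes higher (9 adjusted over the list alone), among them the immunoproteasome subunits Psmb9 (3.95 ± 0.32) and Psmb8 (3.55 ± 0.33; adjusted p = 7.94e-08 for the list, and adjusted p = 0.224 with an estimated correlation). Of 22 immediate early and stress genes, 11 rose and 0 fell (11 adjusted over the list alone), led by Atf3 (4.64 ± 0.66) and Nr4a1 (3.34 ± 0.38), both transcription factors induced by stress or stimulation (adjusted p = 0.00334, and adjusted p = 0.671 with an estimated correlation). Cytokine receptors were higher in 9 and lower in 1 of 15 (11 and 1 adjusted over the list alone; adjusted p = 0.00115, and adjusted p = 0.277 with an estimated correlation). Adhesion and homing genes were higher in 7 and lower in 1 of 14 (7 and 1 adjusted over the list alone; adjusted p = 0.0236, and adjusted p = 0.288 with an estimated correlation). BMP and TGF-beta genes were higher in 7 and lower in 1 of 17 (7 and 1 adjusted over the list alone; adjusted p = 0.0422, and adjusted p = 0.444 with an estimated correlation).

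Cell cycle genes fell in 18 of 32 and rose in 1 (18 and 1 adjusted over the list alone; adjusted p = 0.00133, and adjusted p = 0.671 with an estimated correlation), including the replication helicase gene Mcm4 (-0.99 ± 0.20). The fetal and embryonic programme fell in 6 of 9 (7 adjusted over the list alone; adjusted p = 0.00343, and adjusted p = 0.396 with an estimated correlation). Hepatocyte and visceral endoderm markers were lower in 8 of 13 (9 adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.671 with an estimated correlation), and their mean level ranged from 5.01 to 8.85 over the yolk sac arrays. Core stem cell transcription factors went both ways, with 4 higher and 9 lower of 19 and no call for the list (adjusted p = 0.114). Hoxa9 rose by 3.14 ± 0.80, while Gfi1b fell by 2.85 ± 0.36, Erg by 2.20 ± 0.64 and Meis1 by 1.96 ± 0.44. Kit itself was lower in AGM (-2.52 ± 0.72, adjusted p = 0.00517). In all, 5205 of 13134 genes differed, 2487 higher and 2718 lower in AGM. With renewed quantile normalization 2839 were higher and 2278 lower, so the balance of directions depended on the scaling. Within the Nugen arrays, 6 against 2, 2968 genes differed, 1187 higher and 1781 lower.

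Placenta and AGM, both labelled specifying, were compared as 2 sites of emerging blood cells. Some MHC class II genes, which present antigen on professional antigen-presenting cells, were higher in placenta. H2-Aa rose by 6.74 ± 0.48 on the log2 scale, 107-fold (adjusted p = 1.3e-13, n = 6 and 6), and H2-Ab1 by 4.67 ± 0.42, 25.4-fold. Macrophage genes fell, among them Mrc1, the mannose receptor (-5.04 ± 0.94), and C1qa (-4.98 ± 0.97). Of 7 MHC class II genes, 5 rose and 0 fell (5 adjusted over the list alone; adjusted p = 4.76e-06, and adjusted p = 0.221 with an estimated correlation). Of 22 myeloid and macrophage markers, 12 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.000164, and adjusted p = 0.581 with an estimated correlation). Immediate early and stress genes fell in 11 of 22 (12 adjusted over the list alone; adjusted p = 0.00202, and adjusted p = 0.671 with an estimated correlation), such as Fos (-2.02 ± 0.73).

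Markers of trophoblast, the placenta's own lineage, were higher in 5 of 8 (5 adjusted over the list alone; adjusted p = 0.00719, and adjusted p = 0.671 with an estimated correlation). Tpbpa rose by 3.94 ± 0.59 and Rhox9 by 2.93 ± 0.53. The list's mean level ranged from 4.63 to 9.32 over the placenta arrays. Megakaryocyte and platelet markers were higher in 8 and lower in 1 of 15 (8 and 1 adjusted over the list alone; adjusted p = 0.0135, and adjusted p = 0.564 with an estimated correlation). Kit (2.70 ± 0.68), Erg (2.27 ± 0.60) and Myb (1.55 ± 0.46) were higher in placenta, and Spi1, the regulator of myeloid fate known as PU.1, was lower (-1.21 ± 0.27). In all, 3865 genes differed, 2213 higher and 1652 lower, and 1904 and 1960 with renewed quantile normalization. Within the Nugen arrays, 3 against 6, the count was 4064, 2670 higher and 1394 lower. Control probe sets of RNA integrity moved with the groups: the log2 difference between the 3' and 5' ends of Actb was 1.06 to 1.25 on placenta replicates 2, 4, 5 and 6, 0.49 and 0.23 on replicates 1 and 3, and 0.24 to 0.55 in AGM. That of Gapdh was 1.39 to 3.39 in placenta and 0.62 to 1.74 in AGM. Without those 4 placenta arrays, a choice made after the data were seen, 928 genes differed, 414 higher and 514 lower, with 2 placenta arrays left. H2-Aa (8.06 ± 0.61) and Tpbpa (6.59 ± 0.48) were then called. C1qa went from -4.98 ± 0.97 to -3.40 ± 1.43 (adjusted p = 0.158), Fos from -2.02 ± 0.73 to -0.93 ± 1.08 (adjusted p = 0.682) and Kit from 2.70 ± 0.68 to 2.31 ± 1.08 (adjusted p = 0.213). Erg (1.23 ± 0.92, adjusted p = 0.48), Myb (0.64 ± 0.71, adjusted p = 0.666) and Spi1 (-0.96 ± 0.40, adjusted p = 0.155) lost their limma calls too. For C1qa, Fos, Kit, Erg, Myb and Spi1 the SE grew with fewer arrays and the difference was smaller. The differences of H2-Aa and Tpbpa were larger than with all arrays (6.74 ± 0.48 and 3.94 ± 0.59). How far RNA integrity played a part was not tested. AGM replicates 3, 4 and 5 had the lowest Kit and Cdh5 levels of that group, and without them, a choice made after the data were seen, 2052 genes differed.

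FL12.5 was compared with AGM to follow the arrival of stem cells in the fetal liver. Genes of acute activation were far lower in FL12.5. The chemokine Cxcl2 fell by 7.41 ± 0.48 on the log2 scale (adjusted p = 2.35e-15, n = 6 and 6), and Ptgs2, the inducible cyclooxygenase, by 6.76 ± 0.43. The immediate early factors Fosb (-6.38 ± 0.59), Egr2 (-6.36 ± 0.53) and Fos (-6.03 ± 0.69) fell with them. Hemgn, a nuclear protein of blood progenitors, rose 12.3-fold (3.62 ± 0.32, adjusted p = 2.39e-11). Of 22 immediate early and stress genes, 21 fell and 0 rose (21 adjusted over the list alone), with a median of -3.49 and an adjusted p of 3.56e-40. This was the only call of 76 that held with an estimated correlation, where its adjusted p = 0.000709. The list's mean level was high in placenta (10.1) and yolk sac (9.85) as well as in AGM (11.0), against 7.30 in FL12.5. Genes induced by stress or stimulation can vary with handling of the cells. Handling was not tested, so the fall cannot be assigned to cell stage, and the same limit holds for this list in the other comparisons.

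Myeloid and macrophage markers fell in 15 of 22 (20 adjusted over the list alone; adjusted p = 1.32e-12, and adjusted p = 0.161 with an estimated correlation), with Mrc1 at -5.37 ± 0.89 and C1qb at -5.35 ± 1.07. FL12.5 replicates 2 and 3 did not share this fall, with list means of 9.68 and 9.45 inside the AGM range (9.10 to 10.42), while the other FL12.5 arrays lay between 6.17 and 6.49. Mast cell and basophil markers fell in 4 of 7 (4 adjusted over the list alone; adjusted p = 0.000342, and adjusted p = 0.299 with an estimated correlation), including Cpa3, a mast cell protease (-2.99 ± 0.44). Cytokine receptors fell in 5 and rose in 1 of 15 (5 and 2 adjusted over the list alone; adjusted p = 0.0178, and adjusted p = 0.529 with an estimated correlation). Hoxa9 (2.09 ± 0.71), Erg (1.98 ± 0.57), Mllt3 (1.16 ± 0.41) and Bmi1 (1.05 ± 0.21) were among 6 core stem cell transcription factors that rose, and Spi1 was the 1 that fell (-1.14 ± 0.25). The list itself was not called (adjusted p = 0.0855). In all, 2685 genes differed, 1466 higher and 1219 lower. With only the groups compared, 1107 differed, 516 higher and 591 lower, and array weights gave 8429.

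With only the 4 FL12.5 arrays labelled definitive, 5320 genes differed, 3300 higher and 2020 lower. Core stem cell transcription factors then rose in 14 of 19 and fell in 1 (adjusted p = 8.05e-07, and adjusted p = 0.294 with an estimated correlation). Hoxa9 was higher by 3.95 ± 0.47, Erg by 3.36 ± 0.42 and Kit by 2.99 ± 0.33. Hoxa genes rose in 4 of 5 (adjusted p = 0.014, and adjusted p = 0.267 with an estimated correlation), and adult stem cell genes rose in 11 and fell in 2 of 20 (adjusted p = 0.00544, and adjusted p = 0.656 with an estimated correlation). The stress list fell in 21 of 22 there too, with a median of -3.79 (adjusted p = 5.81e-22). Its call was lost with an estimated correlation (adjusted p = 0.0689). With the 2 arrays labelled specifying alone, 1621 genes differed, and Kit was lower than in AGM (-2.52, adjusted p = 5.18e-05). Hoxa9 (-1.63), Erg (-0.77) and Mllt3 (-0.59) then had the opposite sign and were not called, and C1qc (0.25) and Csf1r (0.0155) did not fall. Without AGM replicates 3, 4 and 5, with all FL12.5 arrays, 1079 genes differed, 437 higher and 642 lower, a count chosen after the data were seen. The log2 difference between the 3' and 5' ends of Actb was 0.81 to 0.91 on FL12.5 replicates 4, 5 and 6, and 0.24 to 0.55 in AGM. Without those 3 arrays, also chosen after the data were seen, 1047 genes differed, 434 higher and 613 lower, and the arrays labelled specifying were then 2 of 3.

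FL13.5 was compared with FL12.5, successive days whose sort gates differ. Few genes passed the test. Dkk1, a secreted Wnt inhibitor, rose by 2.62 ± 0.36 on the log2 scale, 6.15-fold (adjusted p = 5.47e-05, n = 4 and 6), and the transcription factor Dach1 by 2.47 ± 0.34, 5.55-fold. The myeloid genes Csf1r, a growth factor receptor of macrophages (-3.87 ± 0.72), and Fcgr3, an Fc receptor (-3.34 ± 0.61), fell. Slamf1, a sort marker at day 13.5 only, rose by 1.92 ± 0.33 (adjusted p = 0.00127), and Cd48, sorted against on that day, fell by 1.54 ± 0.39 (adjusted p = 0.0286). Adult stem cell genes rose in 4 of 20, and in 12 adjusted over the list alone (adjusted p = 4.77e-08, and adjusted p = 0.239 with an estimated correlation). Core stem cell transcription factors rose in 2 of 19, Mllt3 (2.01 ± 0.45) and Tal1 (1.51 ± 0.36), and in 12 adjusted over the list alone (adjusted p = 1.34e-07, and adjusted p = 0.507 with an estimated correlation).

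Myeloid and macrophage markers fell in 2 of 22 on that day (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.00027, and adjusted p = 0.586 with an estimated correlation). Glycolysis and hypoxia genes fell in 1 of 17, the hexokinase gene Hk2 (-1.14 ± 0.23; 2 adjusted over the list alone; adjusted p = 0.000936, and adjusted p = 0.512 with an estimated correlation). Immediate early and stress genes fell in 2 of 22 (5 adjusted over the list alone; adjusted p = 0.00202, and adjusted p = 0.671 with an estimated correlation), and cytokine receptors in 2 of 15 (2 adjusted over the list alone; adjusted p = 0.0149, and adjusted p = 0.512 with an estimated correlation). Ribosomal protein genes were called higher as a list with 0 of 19 members called, also 0 adjusted over the list alone (median 0.15, adjusted p = 0.00193, and adjusted p = 0.671 with an estimated correlation). In all, 256 genes differed, 132 higher and 124 lower, against 8 with only the groups compared and 4033 with array weights. With a stricter filter 112 were higher and 126 lower, and with the mean of the probe sets 211 and 149. The balance of directions thus depended on the processing. The Actb 3' to 5' difference was 0.81 to 0.91 on FL12.5 replicates 4, 5 and 6 and 0.09 to 0.47 in FL13.5, and without those 3 arrays, a choice made after the data were seen, 2579 genes differed. The count was 761, 87, 91, 501, 431 and 442 without FL12.5 replicates 1 to 6 in turn, and 115, 109, 110 and 56 without FL13.5 replicates 1 to 4. With only the FL12.5 arrays labelled definitive, the core stem cell transcription factors had 0 of 19 members called and no call (median 0.15, adjusted p = 0.148). The calls of the myeloid and macrophage markers (median -0.08, adjusted p = 0.449) and of the cytokine receptors (1 of 15 lower, adjusted p = 0.434) were lost too. Adult stem cell genes rose in 1 of 20 there (adjusted p = 0.000175, and adjusted p = 0.464 with an estimated correlation). In that fit 80 genes differed, Dkk1 and Dach1 remained called (1.91 ± 0.24 and 2.05 ± 0.33), and Mllt3 (1.14 ± 0.37, adjusted p = 0.139) and Tal1 (0.63 ± 0.21, adjusted p = 0.146) were not.

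FL14.5 was compared with FL13.5, successive days with the same sort gate. Pdgfc, a growth factor gene, rose by 1.99 ± 0.40 on the log2 scale, 3.97-fold (adjusted p = 0.00909, n = 6 and 4), and Wfdc18 by 1.60 ± 0.37. Tespa1, a gene of lymphocyte signalling, fell by 2.28 ± 0.60 and Mgam, an intestinal enzyme gene, by 2.12 ± 0.44. Cell cycle genes were lower as a list, with 3 of 32 lower and 0 higher (16 lower adjusted over the list alone; median -0.50, adjusted p = 2.12e-07, and adjusted p = 0.444 with an estimated correlation). The mitotic kinase gene Aurkb fell by 1.20 ± 0.27 and Rrm1, a ribonucleotide reductase subunit, by 0.90 ± 0.19. In all, 141 genes differed, 21 higher and 120 lower, against 1567 with only the groups compared, 1608 with array weights, 301 without the amplification term and 68 with renewed quantile normalization. Within the Nugen arrays, 3 against 4, 262 genes differed, 27 higher and 235 lower. The count was 14, 45 and 46 without FL13.5 replicates 1, 2 and 3, and 68, 90, 42 and 56 without FL14.5 replicates 2, 3, 4 and 6.

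Bone marrow was compared with FL14.5 to set adult against fetal stem cells. Among the genes with the largest changes, H2-Aa, an MHC class II gene, rose by 6.33 ± 0.48, 80.2-fold (adjusted p = 5.79e-13, n = 5 and 6), and Aldh1a1, a retinaldehyde dehydrogenase, by 6.29 ± 0.24, 78.1-fold. Hmga2, an architectural chromatin protein of fetal cells, fell by 4.29 ± 0.60, and Igf2bp1, an RNA-binding protein of the embryo, by 4.48 ± 0.27. Hbb-y, an embryonic globin gene, fell by 5.28 ± 1.23. Cell cycle genes fell in 17 of 32 and rose in 0 (19 adjusted over the list alone; adjusted p = 2.44e-12, and adjusted p = 0.221 with an estimated correlation), with Birc5 at -1.72 ± 0.17 and the cyclin gene Ccnb2 at -1.67 ± 0.20. MHC class II genes rose in 5 of 7 (7 adjusted over the list alone; adjusted p = 5.42e-11, and adjusted p = 0.0689 with an estimated correlation). MHC class I genes rose in 8 of 11 (10 adjusted over the list alone; adjusted p = 2.21e-08, and adjusted p = 0.221 with an estimated correlation), among them the transactivator Nlrc5 (2.98 ± 0.44).

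The fetal and embryonic programme fell in 5 of 9 from FL14.5 to bone marrow (5 adjusted over the list alone; adjusted p = 8.29e-08, and adjusted p = 0.0689 with an estimated correlation). Interferon response genes rose in 9 of 28 (9 adjusted over the list alone; adjusted p = 3.96e-06, and adjusted p = 0.671 with an estimated correlation), with Iigp1 at 2.61 ± 0.40. Immediate early and stress genes rose in 9 of 22 (11 adjusted over the list alone; adjusted p = 9.26e-05, and adjusted p = 0.529 with an estimated correlation), with Egr1 at 3.75 ± 0.43. Imprinted genes fell in 4 and rose in 1 of 20 (5 and 2 adjusted over the list alone; adjusted p = 0.0171, and adjusted p = 0.706 with an estimated correlation), including Igf2, the fetal growth factor (-4.01 ± 0.67), and Plagl1 (-3.77 ± 0.62). Oxidative phosphorylation genes fell in 2 of 20 (1 adjusted over the list alone; adjusted p = 0.0467, and adjusted p = 0.815 with an estimated correlation). Of 19 core stem cell transcription factors, Gfi1b rose (1.12 ± 0.34), Gfi1 fell (-2.22 ± 0.72), and the list was not called (adjusted p = 0.406). In all, 1822 genes differed, 949 higher and 873 lower, and 958 and 1075 with renewed quantile normalization. The count was 866 within the Nugen arrays (3 against 3), 417 higher and 449 lower, and 875 within the arrays with no kit named (2 against 3), 591 higher and 284 lower. Xist was called lower in bone marrow, but its levels there were 11.60 on replicate 5 and under the filter value on the other replicates, so no average difference is given.

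**Figure D3:**
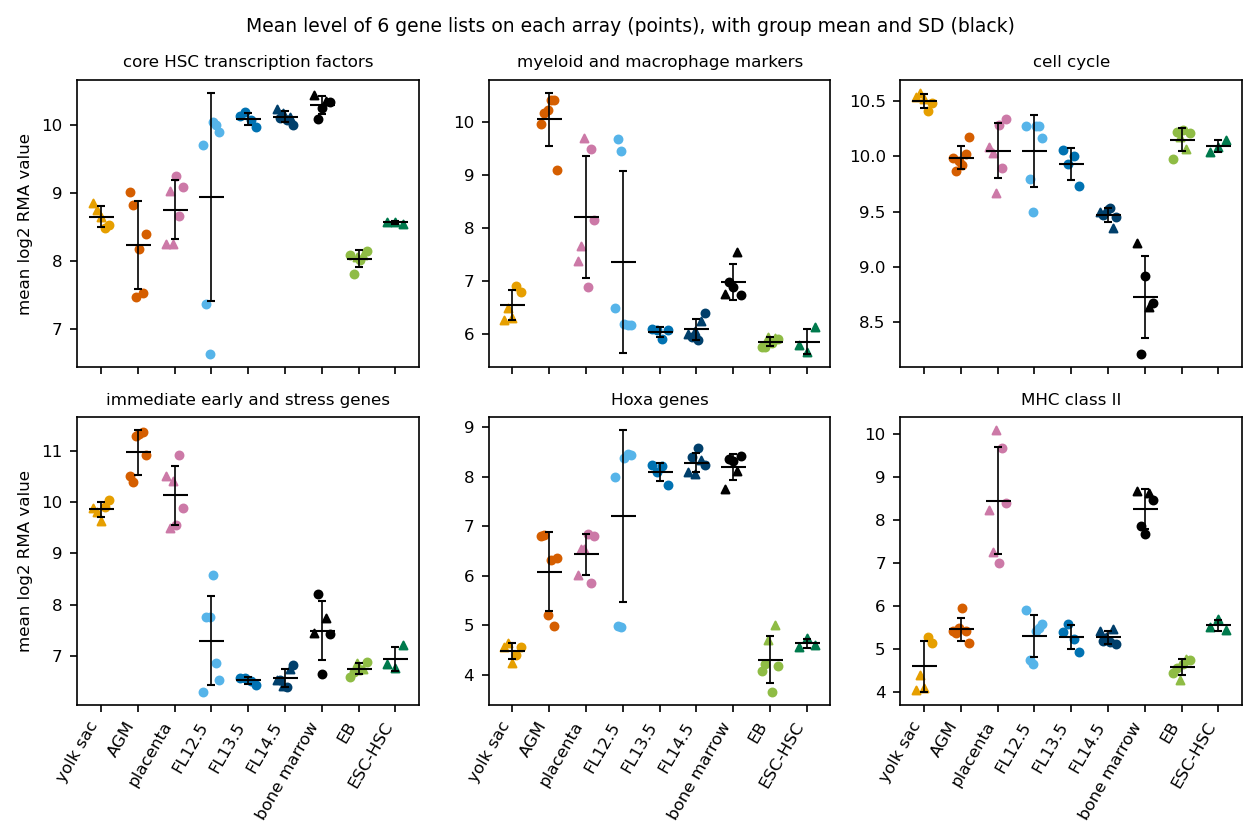
Mean log2 RMA value of 6 gene lists on each array, as points by group (circles for the Nugen kit, triangles for no kit named), with the group mean and SD in black. The immediate early and stress list had group means of 11.0 in AGM, 10.1 in placenta and 9.85 in yolk sac, and all other group means lay between 6.53 and 7.50.

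EB cells were compared with yolk sac cells, the in vitro and in vivo cells of the yolk-sac-like stage. The largest falls in EB included stress genes. How far handling of the cells played a part was not tested. Fos fell by 7.53 ± 0.74 on the log2 scale (adjusted p = 1.42e-10, n = 6 and 5), and the heat shock gene Hspa1a by 6.68 ± 0.76. The largest rises held Scd1, a fatty acid desaturase (5.55 ± 1.01, 46.8-fold), the extracellular matrix gene Reln (4.90 ± 0.32) and Unc5c, a netrin receptor (4.61 ± 0.27). Ptprc, the gene of the CD45 surface protein, was lower in EB by a log2 difference of -3.48 ± 0.42. Of 22 immediate early and stress genes, 19 fell and 1 rose (20 and 1 adjusted over the list alone; adjusted p = 2.39e-15, and adjusted p = 0.0689 with an estimated correlation). Hepatocyte and visceral endoderm markers fell in 9 of 13 (10 adjusted over the list alone; adjusted p = 0.000164, and adjusted p = 0.497 with an estimated correlation). Afp (-4.56 ± 0.87) had an SD of 3.03 over the yolk sac arrays. Adhesion and homing genes fell in 10 of 14 (10 lower and 1 higher adjusted over the list alone; adjusted p = 0.000307, and adjusted p = 0.0689 with an estimated correlation), with the integrin gene Itgal at -2.55 ± 0.27.

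Erythroid markers were higher in EB in 8 of 14 and lower in 0 (8 adjusted over the list alone; adjusted p = 0.0163, and adjusted p = 0.671 with an estimated correlation). Hbb-bh1, an embryonic globin gene, rose by 3.11 ± 0.96 and Klf1, the erythroid master regulator, by 2.57 ± 0.41. Cell cycle genes went both ways, 14 lower and 4 higher of 32 (15 and 4 adjusted over the list alone; adjusted p = 0.0178, and adjusted p = 0.838 with an estimated correlation). Ribosomal protein genes rose in 10 of 19 (10 adjusted over the list alone; adjusted p = 0.0417, and adjusted p = 0.844 with an estimated correlation), with Rps19 at 1.19 ± 0.16. Tal1 (1.43 ± 0.34) and Mllt3 (1.22 ± 0.43) were higher, while Meis1 (-2.15 ± 0.41), Notch1 (-1.52 ± 0.27) and Gata2 (-1.37 ± 0.45) were lower. The core stem cell transcription factors were not called as a list (2 higher and 5 lower of 19, adjusted p = 0.103). In all, 4857 genes differed, 2380 higher and 2477 lower, and 2586 and 2090 with renewed quantile normalization. The count was 1663 within the Nugen arrays (4 against 2), 646 higher and 1017 lower, and 5159 within the arrays with no kit named (2 against 3), 2795 higher and 2364 lower. Without yolk sac replicates 1 and 3, which had high visceral endoderm markers, 3197 genes differed, a count chosen after the data were seen.

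ESC-HSC were compared with FL14.5 to set cultured against fetal cells of the definitive stage. Some stem cell transcription factors were lower in culture, and others were higher. Mecom, a transcription factor needed by long-term stem cells, fell by 8.15 ± 0.88 on the log2 scale (adjusted p = 1.11e-09, n = 3 and 6), Hoxa9 by 7.99 ± 0.91 and Prdm16 by 5.17 ± 0.60. Their ESC-HSC means, 3.41, 3.25 and 4.28, lay under the filter value of 5.14, so these differences are taken against signal near background. Gzmb, which encodes granzyme B, was 264-fold higher (8.04 ± 0.38), and Cst7, a protease inhibitor, 214-fold higher (7.74 ± 0.58). Pdzph1 was 512-fold higher (9.00 ± 0.31). Adult stem cell genes fell in 13 of 20 and rose in 0 (14 adjusted over the list alone; adjusted p = 7.87e-08, and adjusted p = 0.25 with an estimated correlation), including Cdkn1c, an inhibitor of the cell cycle (-4.84 ± 0.65), and Pdzk1ip1 (-4.45 ± 0.36). Core stem cell transcription factors fell in 7 and rose in 3 of 19 (7 and 3 adjusted over the list alone; adjusted p = 0.0355, and adjusted p = 0.885 with an estimated correlation). Those that rose were Gfi1b (1.85 ± 0.41), Runx1 (1.84 ± 0.46) and Tal1 (1.23 ± 0.41).

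Hoxa genes were lower in ESC-HSC than in FL14.5 in 4 of 5 (5 adjusted over the list alone; adjusted p = 0.000569, and adjusted p = 0.221 with an estimated correlation). Hoxb genes were lower in 4 of 5 as well (4 adjusted over the list alone; adjusted p = 0.0106, and adjusted p = 0.147 with an estimated correlation). Endothelial markers fell in 8 of 19 (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.000563, and adjusted p = 0.643 with an estimated correlation), with Emcn at -5.42 ± 0.91. Glycolysis and hypoxia genes rose in 10 of 17 (12 adjusted over the list alone; adjusted p = 9.71e-07, and adjusted p = 0.221 with an estimated correlation), with Pgam1 at 1.40 ± 0.20. Cell cycle genes rose in 15 and fell in 1 of 32 (17 and 1 adjusted over the list alone; adjusted p = 2.79e-05, and adjusted p = 0.581 with an estimated correlation), with the mitotic kinase gene Plk1 at 2.09 ± 0.23. Imprinted genes fell in 10 and rose in 2 of 20 (11 and 2 adjusted over the list alone; adjusted p = 0.00124, and adjusted p = 0.589 with an estimated correlation), with Plagl1 at -6.09 ± 0.75 and Mest at 5.55 ± 0.68. The interferon response list (6 lower and 1 higher of 28; 6 and 1 adjusted over the list alone) had adjusted p = 0.00468, and adjusted p = 0.856 with an estimated correlation. The megakaryocyte list (6 higher and 2 lower of 15; 6 and 2 adjusted over the list alone) had adjusted p = 0.0078, and adjusted p = 0.512 with an estimated correlation. Lymphoid markers fell in 5 and rose in 1 of 15 (5 and 1 adjusted over the list alone; adjusted p = 0.0244, and adjusted p = 0.52 with an estimated correlation), and cytokine receptors fell in 7 and rose in 3 of 15 (7 and 3 adjusted over the list alone; adjusted p = 0.0417, and adjusted p = 0.589 with an estimated correlation). In all, 3011 genes differed, 1511 higher and 1500 lower, with 1342 and 1594 after renewed quantile normalization and 1750 and 1287 after median centring, and 3488 within the arrays with no kit named (3 against 3), 1525 higher and 1963 lower.

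ESC-HSC were also compared with bone marrow, the adult cells of the same stage name. Mecom fell by 8.14 ± 0.92 on the log2 scale (adjusted p = 2.94e-09, n = 3 and 5), Hoxa9 by 7.80 ± 0.95 and H2-Aa by 6.93 ± 0.61. The peptide hormone receptor gene Mc2r rose by 7.17 ± 0.23 (144-fold), Npy, a neuropeptide gene, by 6.72 ± 0.36 (105-fold) and Gzmb by 7.72 ± 0.40 (211-fold). Cell cycle genes rose in 21 of 32 and fell in 0 (26 adjusted over the list alone; adjusted p = 4.22e-14, and adjusted p = 0.172 with an estimated correlation), with Plk1 at 3.15 ± 0.24 and Aurkb at 2.83 ± 0.31. Adult stem cell genes fell in 15 of 20 (15 adjusted over the list alone; adjusted p = 3.67e-10, and adjusted p = 0.172 with an estimated correlation), with Sult1a1 at -5.05 ± 0.37. Interferon response genes fell in 11 of 28 (16 adjusted over the list alone; adjusted p = 9.11e-08, and adjusted p = 0.586 with an estimated correlation), with Iigp1 at -5.96 ± 0.51. Glycolysis and hypoxia genes rose in 14 and fell in 1 of 17 (15 and 1 adjusted over the list alone; adjusted p = 9.71e-07, and adjusted p = 0.221 with an estimated correlation).

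MHC class II genes were lower in ESC-HSC than in bone marrow in 5 of 7 (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.000532, and adjusted p = 0.402 with an estimated correlation). MHC class I genes were lower in 7 of 11 (8 adjusted over the list alone; adjusted p = 0.00176, and adjusted p = 0.589 with an estimated correlation), with Nlrc5 at -3.85 ± 0.55. Hoxa genes fell in 3 of 5 (5 adjusted over the list alone; adjusted p = 0.00202, and adjusted p = 0.273 with an estimated correlation) and Hoxb genes in 4 of 5 (4 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.147 with an estimated correlation). Oxidative phosphorylation genes rose in 7 of 20 (7 adjusted over the list alone; adjusted p = 0.004, and adjusted p = 0.671 with an estimated correlation). Core stem cell transcription factors fell in 7 and rose in 1 of 19, Runx1 at 1.72 ± 0.48 (8 and 1 adjusted over the list alone; adjusted p = 0.0078, and adjusted p = 0.831 with an estimated correlation). Endothelial markers fell in 7 and rose in 1 of 19 (7 and 1 adjusted over the list alone; adjusted p = 0.0321, and adjusted p = 0.838 with an estimated correlation). In all, 3369 genes differed, 1663 higher and 1706 lower, and 3078 within the arrays with no kit named (3 against 2), 1080 higher and 1998 lower. With only the groups compared, 988 were higher and 2017 lower, and with median centring 1927 and 1481, so the balance of directions depended on the fit.

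The change in culture, from EB to ESC-HSC, was set against the change in the animal, from yolk sac to bone marrow, by testing their difference. These changes share no arrays. An upward difference can come from a rise in culture or from a fall in the animal. Itgal, an integrin of leukocytes, gained more in culture by 7.34 ± 0.43 on the log2 scale (adjusted p = 9.25e-17, n = 3, 6, 5 and 5). Iigp1 gained less by -7.01 ± 0.66 and Pdzk1ip1 by -7.52 ± 0.50. Cell cycle genes differed upward in 25 and downward in 1 of 32 (26 and 2 adjusted over the list alone; median 1.80, adjusted p = 9.69e-14, and adjusted p = 0.172 with an estimated correlation). Interferon response genes differed downward in 13 of 28 (19 adjusted over the list alone; median -2.15, adjusted p = 1.13e-07, and adjusted p = 0.586 with an estimated correlation). Immediate early and stress genes differed upward in 17 and downward in 1 of 22 (18 and 1 adjusted over the list alone; adjusted p = 9.3e-07, and adjusted p = 0.365 with an estimated correlation), with Fos at 6.38 ± 1.21. The mean level of the stress list was 6.75 in EB, 6.94 in ESC-HSC, 9.85 in yolk sac and 7.50 in bone marrow. For the cell cycle list it was 10.15, 10.09, 10.51 and 8.73 in that order. Both lists were nearly level in culture and fell in the animal. How far handling of the cells played a part in the stress list was not tested. Adult stem cell genes differed downward in 12 of 20 (12 adjusted over the list alone; adjusted p = 2.68e-06, and adjusted p = 0.365 with an estimated correlation), and glycolysis and hypoxia genes upward in 12 and downward in 1 of 17 (13 and 1 adjusted over the list alone; adjusted p = 4.36e-06, and adjusted p = 0.258 with an estimated correlation).

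Hoxb genes differed downward in 4 of 5 between the changes (4 adjusted over the list alone; adjusted p = 0.00343, and adjusted p = 0.0689 with an estimated correlation), with Hoxb5 at -5.11 ± 0.72. Hoxa genes differed downward in 3 of 5 (4 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.497 with an estimated correlation). MHC class I genes did so in 5 of 11 (6 adjusted over the list alone; adjusted p = 0.00417, and adjusted p = 0.671 with an estimated correlation) and MHC class II genes in 5 of 7 (5 adjusted over the list alone; adjusted p = 0.00588, and adjusted p = 0.576 with an estimated correlation). Upward differences were called in 4 of 9 genes of the fetal and embryonic programme (4 adjusted over the list alone; adjusted p = 0.0273, and adjusted p = 0.581 with an estimated correlation). Megakaryocyte markers differed upward in 5 and downward in 1 of 15 (6 and 1 adjusted over the list alone; adjusted p = 0.0438, and adjusted p = 0.671 with an estimated correlation), and ribosomal protein genes downward in 7 of 19 (9 adjusted over the list alone; adjusted p = 0.0355, and adjusted p = 0.842 with an estimated correlation). Runx1 differed upward (2.63 ± 0.63), and Hoxa9 (-6.63 ± 1.24) and Mecom (-6.46 ± 1.21) downward. In all, 3905 of 13134 genes differed, 1985 upward and 1920 downward, and 4340 within the arrays with no kit named, 1694 upward and 2646 downward. With median centring 2337 differed upward and 1582 downward, so the balance of directions depended on the fit. Across genes, which are not independent replicates, the changes correlated with Pearson's r = 0.299 and Spearman's rho = 0.216. Of 1641 genes called in both changes, 1187 (72.3%) moved the same way. Independent lists would give 280.7 genes higher in both and 380.1 lower in both, and 557 and 630 were observed.

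**Figure D4:**
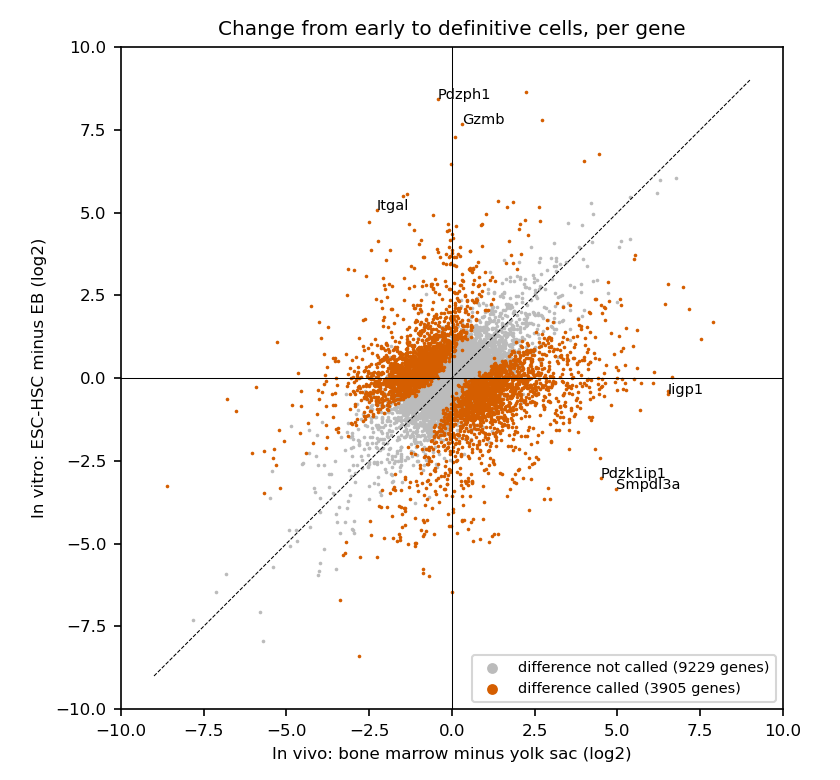
Log2 change of each of 13134 genes from EB to ESC-HSC (vertical) against its change from yolk sac to bone marrow (horizontal), with the 3905 genes whose changes differed in colour and the dashed line of equal change. Across genes, Pearson's r was 0.299.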

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

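The tests of FL12.5 replicates 2 and 3, of the amplification term and of the kit as a source of the macrophage genes were chosen only after the result was seen.

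FL12.5 replicates 2 and 3 stand apart from the other FL12.5 arrays, with Kit at 5.50 and 4.63 and Itga2b at 8.60 on replicate 3 (7.27 to 7.76 on the others), and carry another stage name. A swap with AGM arrays was argued against, since 0 AGM arrays correlated better with the FL12.5 arrays labelled definitive (0.832 to 0.873) than with the other AGM arrays (0.942 to 0.963). The immediate early and stress list had a mean of at most 7.77 on both arrays and at least 10.4 on the AGM arrays (SD 0.43). This sets both apart from the AGM arrays at hand. Genes induced by stress or stimulation can vary with handling, so the list cannot decide whether these are AGM arrays under a fetal liver label. Both arrays had a higher mean correlation with the AGM arrays (0.920 and 0.899) than with the rest of FL12.5 (0.856 and 0.823). The latter means include their correlation with each other, 0.960, the highest of either array. A minority of other cells in the sort was argued against by the core stem cell transcription factors, whose median linear level was 16.9% and 13.2% of the other arrays, which ranged from 76.1% to 118% among themselves. A difference in cell stage, as the labels name it, and a majority of other cells were not tested and stay open.

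Macrophage genes were higher in AGM than in yolk sac, and the gate on VE-cadherin and CD45 would remove macrophages only where they lack VE-cadherin. On the Nugen arrays alone, the macrophage list had a median of 2.90, against 3.33 over all arrays. Values adjusted for the kit before deposit, a candidate explanation raised below, could bring these medians together whatever the kit had done. The comparison therefore cannot decide whether the amplification kit was a source. Macrophages among the sorted AGM cells remain a candidate explanation: of 21 further macrophage genes, outside the fixed lists, 20 (95.2%) were called higher, with a median of 3.61 (p = 0.0704 by camera with an estimated correlation). Of the abundant ones, Ctsb had means of 13.60 and 9.35, Tyrobp 13.13 and 10.88, and Lgmn 10.91 and 5.23 in AGM and yolk sac, while Laptm5, also expressed by other blood cells, was not called (13.07 and 12.80). Expression of these genes by the AGM precursors themselves was not tested and stays open.

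The amplification term was smaller than chance gives, with a median absolute t of 0.0735 over all genes and values between 0.420 and 0.968 in 100 shuffles of the kit labels within groups. By limma, 0 genes were called for it, and 0 had an unadjusted p under 0.05. Kits that give the same values were argued against, since the real value lay below all of the shuffles. Values adjusted for the kit before deposit are a candidate explanation, and if so the p-values could be too small. No biological explanation was tested.

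Single arrays far from the rest of their group were looked for in 160 sets of arrays over 20 measures, and 12 were found, while chance flags about 1 in 20 groups. In placenta, Cdh5 was 9.37 on replicate 1 (4.86 to 6.21 on the others). EB replicate 1 had Kit at 10.26 (9.48 to 9.73) and Itga2b at 10.16 (9.47 to 9.71), and EB replicate 2 had Slamf1 at 4.14 (3.22 to 3.49). In FL13.5 replicate 3, Slamf1 was 6.82 (7.73 to 7.90) and the macrophage list 5.91 (6.08 to 6.11). The macrophage list was 9.10 on AGM replicate 6 (9.96 to 10.42), and Xist was 11.00 on FL14.5 replicate 3 (11.27 to 11.43). Bone marrow replicate 2 had Cd34 at 9.16 (10.05 to 10.41), and bone marrow replicate 5 had Xist at 11.60 (3.58 to 5.04) with Eif2s3y, a Y-linked gene, at 7.51 (9.68 to 10.40). The change in culture differed from the change in the animal in 3905 genes.

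Other splits of the arrays into groups of the same sizes were drawn to see whether chance can be excluded, and the real split is counted among them. The splits take the arrays as independent, which the labels do not state, so each exclusion below holds only under that condition. If values were adjusted for the kit before deposit with the groups kept, the real splits would be favoured. Chance can be excluded for AGM against yolk sac (5205 genes, highest other split 4012, 1 of 100 splits as large), placenta against AGM (3865, highest other 1299), FL14.5 against FL13.5 (141, highest other 4), bone marrow against FL14.5 (1822, highest other 1049) and EB against yolk sac (4857, highest other 3126). It can also be excluded for ESC-HSC against FL14.5 (3011, highest other 1085, 84 splits), ESC-HSC against bone marrow (3369, highest other 1470, 56 splits) and the difference between the changes (3905, highest other 1758). It cannot be excluded for FL12.5 against AGM (2685, highest other 3726, 6 of 100 splits as large) or FL13.5 against FL12.5 (256, highest other 2699, 14 of 100). In these, all of the other 5 and the other 13 splits that called as many genes kept FL12.5 replicates 2 and 3 together, which points to a structure of the samples. With only the FL12.5 arrays labelled definitive, chance can be excluded for both (5320, highest other 4165, and 80, highest other 1, of 35 splits). For the list tests chance cannot be excluded, since 42 of 100 shuffles of the group labels gave at least 76 calls, with a highest other of 101.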

How the results depend on the processing

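The tests without several AGM, yolk sac, placenta or FL12.5 arrays at once were chosen only after the result was seen, and all other alternatives were planned. Counts within 1.5 times of the reported ones are not listed. The cause of the changes below was not tested, except that fewer arrays or more probe sets change what is tested. Fitting only the groups compared also replaces the spread shared over all 9 groups with that of the groups compared.

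Without the amplification term, FL14.5 against FL13.5 gave 301 genes. Within the Nugen arrays, counts were 2968 for AGM against yolk sac, 164 for FL13.5 against FL12.5, 262 for FL14.5 against FL13.5, 866 for bone marrow against FL14.5 and 1663 for EB against yolk sac, and within the arrays with no kit named 875 for bone marrow against FL14.5. Every probe set on its own gave 10629, 7144, 4877, 2818, 9199, 5416, 5993 and 6979 calls for AGM against yolk sac, placenta against AGM, FL12.5 against AGM, bone marrow against FL14.5, EB against yolk sac, ESC-HSC against FL14.5, ESC-HSC against bone marrow and the difference between the changes. Array weights gave 7081 for placenta against AGM, 8429 for FL12.5 against AGM, 4033 for FL13.5 against FL12.5, 1608 for FL14.5 against FL13.5, 3417 for bone marrow against FL14.5, 6693 and 5901 for ESC-HSC against FL14.5 and bone marrow, and 6195 for the difference. Quantile normalization again gave 68 for FL14.5 against FL13.5. Only the groups compared gave 1107 for FL12.5 against AGM, 8 for FL13.5 against FL12.5, 1567 for FL14.5 against FL13.5 and 2839 for bone marrow against FL14.5. FL12.5 arrays labelled definitive alone gave 5320 against AGM and 80 for FL13.5 against them, and those labelled specifying alone 1621 and 4357. Without AGM arrays 3, 4 and 5, placenta against AGM gave 2052 and FL12.5 against AGM 1079, without placenta arrays 2, 4, 5 and 6, which had the larger Actb differences, placenta against AGM gave 928, with 28 of its named genes keeping their side of the threshold and 19 losing their call, without FL12.5 arrays 4, 5 and 6, which had larger Actb differences too, FL12.5 against AGM gave 1047 and FL13.5 against FL12.5 2579, and without yolk sac arrays 1 and 3 EB against yolk sac gave 3197. With an estimated correlation 1 list call was left, and fry called 101 lists, 69 of the 76 and 32 others, while 7 were lost.

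Replicate numbers gave no clear pairing of the arrays. What the fit left over correlated at -0.176 to 0.0420 between same-numbered arrays of AGM and yolk sac. In FL12.5 against AGM it reached 0.361, with 3 of 6 pairs over 0.1, so pairing cannot be ruled out there. With the numbers as a replicate block the counts were 5122, 3576, 2681, 291, 197, 1676, 4828, 2973, 3318 and 3870 in the order of the report, with 77 list calls. Leaving out each array gave 4731 to 5271 genes for AGM against yolk sac, 2783 to 4266 for placenta against AGM, 1841 to 4022 for FL12.5 against AGM, 1391 to 1659 for bone marrow against FL14.5, 4025 to 4878 for EB against yolk sac, 2209 to 2916 for ESC-HSC against FL14.5, 2559 to 3466 for ESC-HSC against bone marrow and 3301 to 4014 for the difference. FL13.5 against FL12.5 ranged from 56 (without FL13.5 replicate 4) to 761 (without FL12.5 replicate 1). Without the other FL12.5 replicates, 2 to 6, it gave 87, 91, 501, 431 and 442, and without FL13.5 replicates 1, 2 and 3 it gave 115, 109 and 110. FL14.5 against FL13.5 ranged from 14 (without FL13.5 replicate 1) to 135, and gave 45 and 46 without FL13.5 replicates 2 and 3, and 68, 90, 42 and 56 without FL14.5 replicates 2, 3, 4 and 6.

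Of the named genes, 569 kept their side of the threshold with median centring and 15 lost their call, and with quantile normalization 566 and 17. Within the Nugen arrays 268 kept it and 100 lost their call, within the arrays with no kit named 306 and 33, with only the groups compared 499 and 62, with the mean of the probe sets 528 and 34, and without AGM arrays 3, 4 and 5 140 and 51. Centring moved the median of all genes in the difference between the changes from -0.03 to 0.10. No list call turned its direction under the alternatives run on lists. These named genes changed sign. Hoxa7 in AGM against yolk sac was -0.24 both within the Nugen arrays and with only the groups compared, where Xist was 0.99. In EB against yolk sac, Oas1a was -0.18 within the Nugen arrays, H2-M3 0.15 and Lfng 0.00465 within the arrays with no kit named, and Tyms 0.15 with the mean of the probe sets. Xaf1 in ESC-HSC against FL14.5 was 0.15 with that mean. Xist in ESC-HSC against bone marrow was 1.76 within the arrays with no kit named, and ranged from -0.71 without bone marrow replicate 1 to 1.24 without bone marrow replicate 5. With the FL12.5 arrays labelled specifying alone, against AGM, C1qc was 0.25, Csf1r 0.0155, Ifnar1 0.17, Kit -2.52, Cd34 -2.34, Erg -0.77, Etv6 -0.66, Gfi1b -0.48, H2-D1 0.16, H2-Ob -0.34, Hoxa10 -0.47, Hoxa9 -1.63, Mfng -0.80 and Mllt3 -0.59. Etv6 was -0.0153 without FL12.5 arrays 4, 5 and 6.

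Signal over background and the number of arrays limit the calls. On simulated data, 77.3% to 97.0% of 4-fold changes, 19.4% to 68.7% of 2-fold changes and 1.49% to 25.4% of 1.5-fold changes were called. There were 3 to 9 false calls per comparison and 0 list calls. The simulated noise was drawn independently for each gene, without the correlation between the genes of a list. The 0 list calls therefore cannot show how often lists are falsely called in the real data.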

Other observations

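The test of p53 target genes was written down before its result was seen, and no test of this part was chosen after it.

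Single genes of the Notch pathway, which is needed for the emergence of blood stem cells, moved without a call for the list by camera in any comparison (15 measured, lowest adjusted p = 0.347, placenta against AGM). There, 2 members rose and 0 fell, also 2 and 0 adjusted over the list alone, and Jag1, a Notch ligand, was higher in placenta by 1.85 ± 0.48 (adjusted p = 0.00387, n = 6 and 6). Notch1 was lower in ESC-HSC than in FL14.5 (-1.99 ± 0.32) and than in bone marrow (-1.44 ± 0.33). Hey1, a target of the pathway, was higher in EB than in yolk sac (1.73 ± 0.53), while Lfng (-1.17 ± 0.38) and Mfng (-1.13 ± 0.36), which modify Notch receptors, were lower. By camera, no comparison called the lists of Wnt targets (7 measured, lowest adjusted p = 0.387), stromal markers (12 measured, lowest adjusted p = 0.0855), pluripotency genes (9 measured, lowest adjusted p = 0.0692) or primitive streak and mesoderm genes (6 measured, lowest adjusted p = 0.108). Fry, which does not compare a list with other genes, called the Notch list in 3 comparisons (lowest adjusted p = 0.000801), Wnt targets in 1 (adjusted p = 0.0224), pluripotency genes in 4 (lowest adjusted p = 3.16e-05), primitive streak and mesoderm genes in 2 (lowest adjusted p = 0.000172) and stromal markers in 0.

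Imprinted genes went both ways in ESC-HSC against bone marrow, with 2 higher and 8 lower of 20 (4 and 8 adjusted over the list alone) and no call for the list (adjusted p = 0.171). Grb10, an inhibitor of growth factor signalling, was lower in ESC-HSC than in bone marrow (-3.70 ± 0.47, adjusted p = 5.03e-08, n = 3 and 5), as were Cdkn1c (-4.03 ± 0.68) and Meg3 (-2.48 ± 0.95). Mest (5.51 ± 0.71) and Peg3 (2.97 ± 0.69) were higher. Dlk1 was higher in FL12.5 than in AGM (2.04 ± 0.43) and lower in bone marrow than in FL14.5 (-2.45 ± 0.45). The mean level of the Hoxa genes was 4.48 ± 0.16 (SD, n = 5) in yolk sac, 6.09 ± 0.80 (n = 6) in AGM, 8.29 ± 0.20 (n = 6) in FL14.5, 4.31 ± 0.47 (n = 6) in EB and 4.64 ± 0.09 (n = 3) in ESC-HSC.

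A hypothesis was that targets of p53, the regulator of the response to DNA damage, are higher in cultured cells. In EB against yolk sac, where 37.0% of all genes were called, 9 of 18 measured targets rose and 2 fell. Their median was 0.45 (unadjusted p = 0.0236 by limma camera with an estimated correlation), a result the hypothesis predicts. Phlda3 (3.09 ± 0.25), Zmat3 (1.80 ± 0.21) and Ccng1 (1.57 ± 0.24) rose, and Pmaip1 (-2.60 ± 0.58) and Tigar (-0.92 ± 0.27) fell. In ESC-HSC against bone marrow, where 25.7% of all genes were called, 6 rose and 2 fell. Their median was 0.47 (unadjusted p = 0.088 by limma camera with an estimated correlation), which leaves the hypothesis open there. In ESC-HSC against FL14.5, for which no prediction was written, 7 rose and 1 fell, with a median of 0.34 (unadjusted p = 0.0577 by the same test). Strain differs between the cultured and the animal cells too, and its effect on these genes was not tested.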
